A study of Arabidopsis thaliana with 6 samples.

How the data were processed

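The samples were 6 libraries of poly(A) RNA from 5-day-old Arabidopsis thaliana seedlings, 3 of WT and 3 of hid1, grouped and numbered by the titles in the labels. Per the labels' protocols, total RNA was isolated with RNeasy kits, libraries were made with the TruSeq RNA kit and sequenced on an Illumina HiSeq system. Per the submitters' processing notes and the design text, the authors mapped the reads to TAIR10 with TopHat2 2.0.9 and called differential genes with Cuffdiff 2.0.0, at more than 2-fold and an adjusted P of at most 0.05. The authors deposited RPKM values, per the file headers, with 1 column per library. The read counter, the gene annotation, the denominator of the RPKM, the treatment of reads that map to several places and the use of strand are not given in the sources used here. RPKM depends on each of these, most of all for gene families, overlapping genes and short RNAs.

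Each table listed 33323 nuclear gene IDs and 0 plastid or mitochondrial IDs, so the planned share of organellar transcripts could not be computed. A total of 32835 IDs were matched to the RefSeq annotation of TAIR10.1, which supplied symbols, biotypes, exon lengths and positions, and 488 were not. The tables hold no coordinates, so the positions printed are those of TAIR10.1 for the same gene ID and were not compared with the build the authors used. The name table held 0 rows for HID1.

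RPKM are not counts, so no count model was used, and the planned settings for counts and for organellar genes did not apply. Depth was estimated from RPKM multiplied by exon length, whose most frequent low value was taken as 1 read. This gave 17.8 to 26.0 M reads per library, as approximations that rest on TAIR10.1 lengths. No gene was at 0 in a single library while at 5 RPKM or more in the other 5.

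Values were tested as log2(RPKM + 1) in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with a mean-variance trend, genotype as the only term, on genes with a mean of at least 1 RPKM in either genotype. P-values were adjusted by the Benjamini-Hochberg method and a gene was called changed at 0.05 or lower. The 15 gene lists were tested with camera at its preset correlation of 0.01, with adjustment over the lists, and beside it with an estimated correlation and with fry. These choices, the lists and the naming rule were fixed before the data were examined. With 3 libraries against 3, an exact permutation test of a single value cannot go below 0.1.

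The rule for named genes took PIF3, PHYB, PIF4, PIF5, HY5 and COP1 whatever their values. It added the 10 largest increases and 10 largest decreases in log2 fold change among genes past the threshold, changed more than 2-fold, with no overlap between the genotypes and a mean of at least 5 RPKM in the higher genotype. From each list it took up to 4 members with the smallest adjusted p, or the 2 with the highest mean where none passed. Other genes named in the closing section were chosen after their values were seen.

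The test was run on simulated libraries made from the WT means and the fitted spread of this comparison, with 50 genes changed at each of 4 sizes, and 18434 genes entered the test. It recovered 18% of 1.5-fold, 68% of 2-fold, 86% of 4-fold and 94% of 8-fold changes, and 7 of its 140 calls were false. Small changes were often missed in this simulation. The real comparison called 2569 genes, which makes its cutoff on the unadjusted p less strict than with 140 calls. The simulated spread was also drawn for each gene on its own. These rates may therefore not carry over to the real comparison.

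The alternatives were pseudocounts of 0.1 and 5, no filter on low values, quantile normalization, the replicate number as a block, and leaving out each library in turn. Median-ratio scaling, removal of a trend with exon length in each library, list tests under the quantile and median-ratio scalings, and the counts of list members under each setting were added after seeing the data. A further 7 lists were written after the largest changes had been seen, and appear only in the closing section. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.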

Results

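Poly(A) RNA was sequenced from whole seedlings of Arabidopsis thaliana, 5 days old, grown in the light condition that the labels call cR (continuous red light, from knowledge of the study). The wild type (WT) and the hid1 (hidden treasure 1) mutant were each represented by 3 libraries, described by the submitters as biological replicates. HID1 is known as a noncoding RNA that promotes photomorphogenesis, the switch from growth in darkness to growth in light, under red light. The value per gene and library was the authors' RPKM, reads per kilobase of gene model scaled to the sequencing depth. A total of 33323 nuclear genes were listed, of which 23009 to 23686 were above 0 in a library. The most frequent low value of RPKM times exon length, taken as 1 read, put the depth at about 20.1, 19.6 and 26.0 M reads for WT replicates 1, 2 and 3, and at about 17.8, 22.5 and 23.3 M reads for hid1 replicates 1, 2 and 3. The depths of the genotypes overlapped. The most abundant transcript in every library was LHCB1.3, a light-harvesting protein of photosystem II, and the top 10 genes held 12.73% to 17.07% of a library's summed RPKM. Values below are mean RPKM ± SD over n = 3 libraries per genotype, and log2 fold changes are hid1 minus WT on the log2(RPKM + 1) scale, with their standard error (SE). That scale understates the change of low genes.

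The comparison of hid1 with WT asks which transcripts differ in seedlings that lack normal HID1 function in red light. The mutated gene itself was not reported by name, because the name table used here pairs no gene ID with HID1. PIF3, a transcription factor that promotes seedling elongation and is degraded after phytochrome senses light, rose from 14.2 ± 2.32 RPKM in WT to 32.4 ± 2.42 in hid1 (log2 fold change 1.14, SE 0.13, limma adjusted p = 0.000409). PHYA, the photoreceptor whose transcript is repressed by light, rose from 42.0 ± 4.33 to 87.4 ± 2.50 (1.04, SE 0.11, adjusted p = 0.000215). PHYB, the main red-light receptor, stood at 17.1 ± 0.671 in WT and 18.1 ± 1.55 in hid1, and the difference did not pass the test (0.07, SE 0.11, adjusted p = 0.719). The related factors PIF4 (41.0 ± 7.92 in WT, 31.0 ± 8.52 in hid1, adjusted p = 0.173) and PIF5 (58.7 ± 4.21 and 54.2 ± 10.6, adjusted p = 0.589) did not pass either. Neither did HY5, a factor that promotes photomorphogenesis (8.38 ± 2.28 and 11.7 ± 1.64, adjusted p = 0.130), or COP1, a ubiquitin ligase that represses it (11.2 ± 0.887 and 13.8 ± 2.69, adjusted p = 0.283). The calls on PIF3 and PHYA held under each of the 13 other settings tried.

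The red-light signalling list had 23 tested members, of which 3 rose, 1 fell and 19 did not pass. The members that rose were PHYA, PIF3 and PKS1, a phytochrome-binding protein (12.4 ± 0.276 to 18.4 ± 2.52, adjusted p = 0.0193). The member that fell was PIF7, a factor of shade growth (18.0 ± 2.64 to 11.8 ± 0.815, adjusted p = 0.0205). Adjusted over the list alone, the count was also 4. As a set the list showed no passing shift in a common direction against other genes (camera adjusted p = 0.84). Members that change in opposite directions can cancel in that test. When direction was disregarded, the list passed fry, which does not compare a list with other genes (adjusted p = 5.55e-05). Most of the fixed lists also passed in that way, so this result does not set the red-light list apart. PKS1 lost its call when WT replicate 2, WT replicate 3 or hid1 replicate 3 was left out (adjusted p up to 0.0622), and PIF7 when WT replicate 2 or 3 or hid1 replicate 2 or 3 was left out (up to 0.0899).

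**Figure D1:**
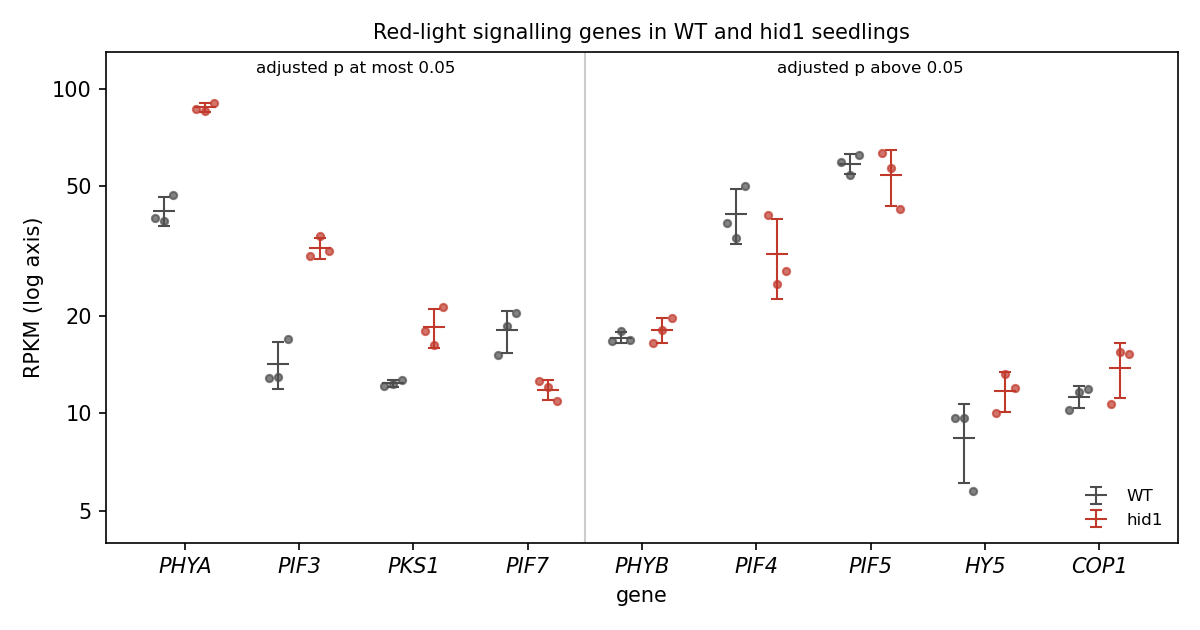
RPKM (log axis) of 9 red-light signalling genes in the 3 WT and 3 hid1 libraries; points are libraries, horizontal marks are means and bars are the SD. PHYA and PIF3 sit higher in every hid1 library than in every WT library (PIF3 14.2 against 32.4 RPKM), whereas the PHYB libraries overlap (17.1 against 18.1 RPKM).

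Of 18871 genes tested with limma, 2569 changed at an adjusted p of at most 0.05, 1775 of them higher in hid1 and 794 lower. The submitters' rule also asks for a change of more than 2-fold, which 643 genes met, 473 higher and 170 lower. The genotypes' libraries did not overlap for 34.6% of tested genes, where chance gives 10%, and for 2544 of the 2569 changed genes. The share of higher genes, 69.1% of the changed genes, depended on the scaling of the libraries. It was 1305 higher against 1343 lower (49.3%) with quantile normalization, 1333 against 1236 (51.9%) with median-ratio scaling and 1427 against 1147 (55.4%) with a length trend removed. The count of changed genes was 1430 without WT replicate 2, 1562 without WT replicate 3, 1517 without hid1 replicate 2 and 1614 without hid1 replicate 3. The first principal component held 58% of the variance and separated the genotypes, while WT replicate 1 lay apart from the other WT libraries on the second (18.1%).

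The largest increase was in SADHU3-2, a pseudogene of the SADHU retroelement family (chromosome 3, 14749400 to 14750294, TAIR10.1 annotation) and uncertain where reads are shared with related copies, from 1.72 ± 0.262 to 23.64 ± 2.54 RPKM (3.18, SE 0.14, adjusted p = 1.59e-06). Among the next were EARLI1 (155.6 ± 35.8 to 1164 ± 390.5) and its neighbour AT4G12500 (22.5 ± 8.51 to 190.5 ± 73.7), both of the lipid-transfer protein family and uncertain because similar copies lie beside each other. The chitinase-family gene AT2G43620 rose from 52.4 ± 5.55 to 434.9 ± 166.4, the peroxidase gene AT5G64120 from 79.9 ± 4.28 to 591 ± 213.9, and the oxygenase gene AT2G36690 from 14.0 ± 1.28 to 107.1 ± 29.7. ASN1, an asparagine synthase induced by darkness and low sugar, rose from 20.4 ± 8.08 to 148.4 ± 39.2, and THA1, a threonine aldolase, from 6.36 ± 2.36 to 47.4 ± 8.74. GH9B15, a glycosyl hydrolase (2.33 ± 1.48 to 21.7 ± 5.47), and ARCK1, a protein kinase (1.12, 2.52 and 1.77 in WT; 12.24, 25.16 and 17.2 in hid1), completed the 10. The adjusted p of these 10 genes was 0.000332 or lower. Each had its 3 hid1 libraries above its 3 WT libraries, which the naming rule required.

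Of the 10 largest decreases, 6 lay in the same cluster on chromosome 4 (AT4G22485, AT4G22505, AT4G22510, AT4G22513, AT4G22517 and AT4G22520), and 5 of those 6 are annotated as lipid-transfer proteins, AT4G22510 as uncharacterized. AT4G22505 (11851155 to 11853018) fell from 120.9 ± 16.8 to 2.27 ± 1.14 RPKM (-5.27, SE 0.21, adjusted p = 1.11e-06), and AT4G22485 from 183.7 ± 38.1 to 6.17 ± 2.86. Values within this cluster are uncertain, since its members are similar and AT4G22510 overlaps AT4G22513 and AT4G22517, and AT4G22520 lies within AT4G22530, on opposite strands. PCC1, a small protein under clock and pathogen control, fell from 51.6 ± 36.0 to 1.27 ± 0.535, and AT3G05727, annotated in a pollen coat protein family, from 50.8 ± 17.1 to 3.11 ± 1.22. The other two were AT2G35747, annotated as a small nucleolar RNA (chromosome 2, 15029832 to 15029911), and AT2G35750, a protein-coding gene whose span (15029829 to 15030348) contains it on the same strand. AT2G35747 was at 16.73, 10.83 and 10.1 RPKM in the WT libraries and AT2G35750 at 10.73, 11.03 and 10.79, and both were listed at 0 in the 3 hid1 libraries. Their reads cannot be told apart from these values. Since the position of HID1 is not in the name table, these features may belong to the locus mutated in hid1, and their values may then show the mutation itself and not a response to it.

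**Figure D2:**
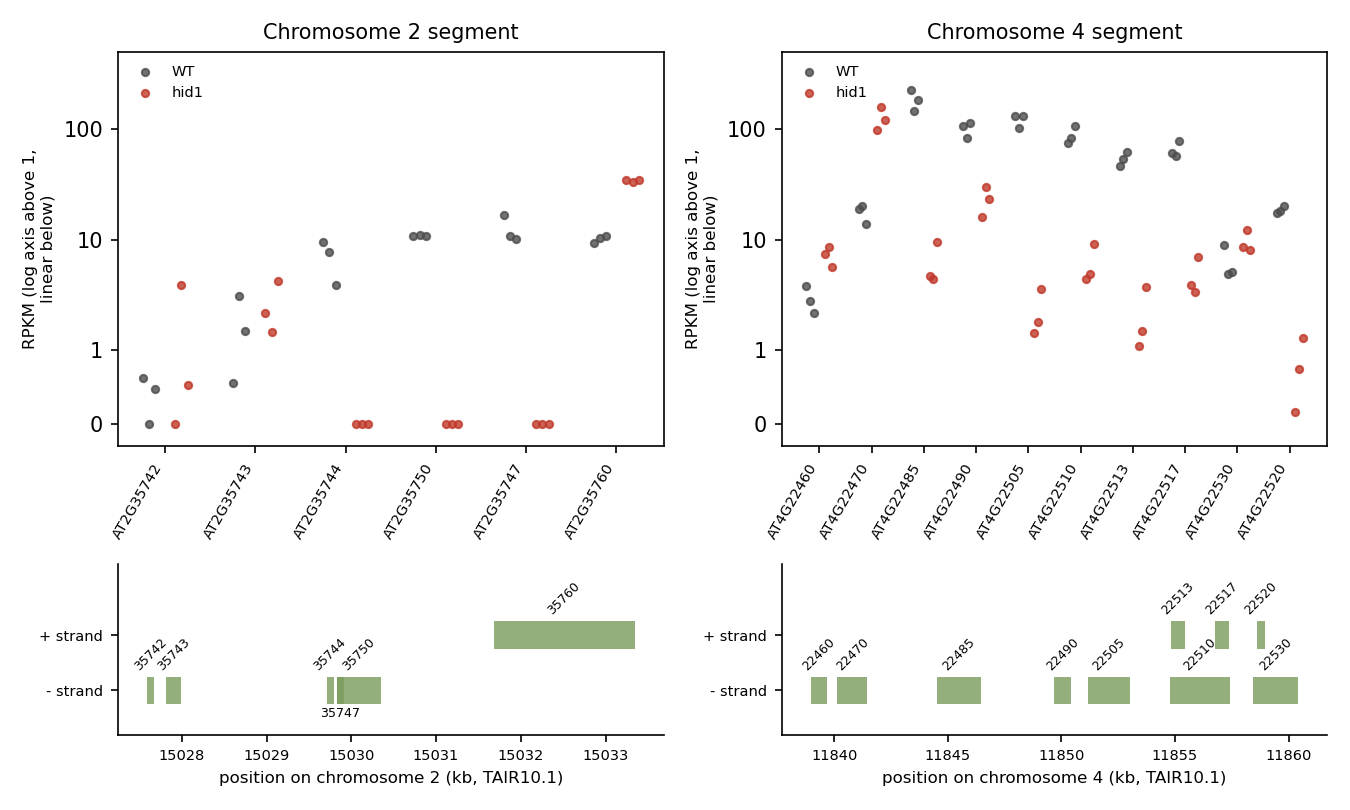
RPKM of each library (upper panels, log axis above 1 and linear below; points are the 3 WT and 3 hid1 libraries) over the segments of chromosomes 2 and 4 that hold 8 of the 10 largest decreases, and the annotated gene spans by strand (lower panels, TAIR10.1). AT2G35747 and AT2G35750 are at 0 in hid1, and AT4G22505 goes from 120.9 to 2.27 RPKM; the neighbours shown beside them were chosen by position.

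Genes of photosynthesis and chlorophyll synthesis were lower in hid1 as sets by camera with its preset correlation. Both set calls were lost with an estimated correlation (camera adjusted p = 0.688 for each list). They were also lost in the self-contained fry test of a common direction (adjusted p = 0.0855 for each). Of 42 nuclear photosynthesis genes, 8 fell, 1 rose and 33 did not pass, with a median log2 fold change of -0.39 (camera adjusted p = 6.99e-11). With 40 of the 42 lower, this median depended on the scaling: it was -0.173 with quantile normalization (33 lower) and -0.472 with median-ratio scaling (41 lower). In the same libraries 7 of 8 root markers other than IRT1 were higher in hid1, 3 of them past the threshold. The mean over the 8 was higher by 0.817 on the log2 scale, but WT replicate 1 (3.48) lay above hid1 replicate 2 (3.44). IRT1 itself fell. LHCB2.3, a light-harvesting protein, fell from 1189 ± 117.7 to 485 ± 203.2 RPKM, PSBQ2 from 1375 ± 51.0 to 903 ± 69.8 and PSBO2 from 1065 ± 67.0 to 719 ± 51.6, the last pair being subunits of the oxygen-evolving complex. LHCB4.3 rose from 12.8 ± 3.08 to 31.9 ± 13.0. Adjusted over the list alone, 16 fell and 1 rose. Of 19 chlorophyll genes, 3 fell, 1 rose and 15 did not pass (median -0.27, camera adjusted p = 0.000505), and adjusted over the list alone 6 fell and 1 rose. PORC, a protochlorophyllide reductase of green tissue, fell from 91.5 ± 8.56 to 48.8 ± 10.1, GSA2 from 121.6 ± 11.3 to 88.1 ± 5.74 and DVR from 50.4 ± 10.4 to 32.9 ± 2.34. PORA, the reductase known for its high level in dark-grown seedlings, rose from 2.76 ± 0.784 to 7.36 ± 1.201. The calls on GSA2, DVR and LHCB4.3 were lost in 4, 5 and 1 of the 13 other settings (adjusted p up to 0.0827, 0.0774 and 0.0594). The number of photosynthesis genes that fell was 5 with quantile normalization or median-ratio scaling and 4 with the length trend removed, and reads of near-identical LHCB and RBCS copies may be split between them.

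Of 26 cell wall loosening genes, 9 rose, 4 fell and 13 did not pass (camera adjusted p = 0.752), and adjusted over the list alone 11 rose and 6 fell. XTH15, a xyloglucan-modifying enzyme, rose from 20.8 ± 3.52 to 85.3 ± 20.6 RPKM (1.97, SE 0.17, adjusted p = 8.90e-05), XTH24 from 62.9 ± 13.7 to 136.4 ± 21.9, and the expansin EXPA17 from 1.89 ± 0.660 to 7.85 ± 1.75, whereas EXPA5 fell from 48.2 ± 3.71 to 26.5 ± 4.95. Of 14 PIF-induced growth and shade genes, 3 rose, none fell and 11 did not pass, the same 3 passing when adjusted over the list alone. They were XTH15, ST2A, a jasmonate-modifying sulfotransferase (3.41 ± 1.04 to 7.82 ± 1.25), and PAR1, a repressor of shade growth (11.6 ± 3.09 to 22.3 ± 4.24). The median of this list was -0.07, its mean 0.18, and camera placed it lower (adjusted p = 0.84) where fry placed it higher (adjusted p = 0.39). Its direction was not stable: the median was 0.006 without hid1 replicate 2, and camera placed it higher without WT replicate 1 or 3 or hid1 replicate 2 or 3. PAR1 lost its call without a filter on low values and without hid1 replicate 2 (adjusted p up to 0.0592).

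Of 28 auxin response genes, 3 rose and 4 fell (camera adjusted p = 0.0854). IAA2 (39.8 ± 5.48 to 64.6 ± 11.5) and IAA4 (22.8 ± 3.02 to 31.3 ± 0.761), repressors of auxin signalling, rose. SAUR20 (10.1 ± 1.61 to 5.34 ± 1.93) and SAUR21 (13.1 ± 1.03 to 7.57 ± 1.25), which lie among similar copies, fell. Adjusted over the list alone, 4 rose and 6 fell. Of 25 brassinosteroid and gibberellin genes, 3 rose and none fell (camera adjusted p = 0.84), and adjusted over the list alone the count was again 3. These were the gibberellin-inactivating GA2OX6 (2.19 ± 0.551 to 4.66 ± 0.783), the gibberellin-producing GA20OX2 (0.783 ± 0.268 to 1.80 ± 0.229) and the receptor gene GID1B (4.32 ± 0.0960 to 6.63 ± 0.229). The calls on GA20OX2, GID1B and GA2OX6 were lost in 8, 5 and 2 of the 13 other settings (adjusted p up to 0.116, 0.0788 and 0.0531), and those on IAA4, SAUR20 and IAA2 in 7, 4 and 2 (up to 0.134, 0.109 and 0.0543).

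Of 19 circadian clock genes, 4 rose, 1 fell and 14 did not pass (camera adjusted p = 0.752), and adjusted over the list alone 6 rose and 2 fell. The 4 that rose were BOA (5.93 ± 0.458 to 11.3 ± 0.542), ELF4 (20.9 ± 3.78 to 37.9 ± 3.72), LUX (25.3 ± 1.91 to 37.2 ± 2.01) and TOC1 (14.2 ± 1.45 to 23.9 ± 4.95), each known to peak toward evening. The hour of harvest of each sample is not given in the sources used here.

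Of 16 flavonoid and anthocyanin genes, 3 rose and 3 fell (camera adjusted p = 0.147; 3 rose and 4 fell adjusted over the list alone). C4H, early in phenylpropanoid synthesis (86.2 ± 12.2 to 124.5 ± 16.8), and MYBL2, a repressor of anthocyanin genes (20.7 ± 7.94 to 37.3 ± 0.488), rose, while LDOX (2.62 ± 0.444 to 1.25 ± 0.327) and GSTF12 (3.62 ± 1.06 to 1.27 ± 0.424), late in anthocyanin synthesis and transport, fell. Of 16 defence and jasmonate genes, 3 rose and 4 fell (camera adjusted p = 0.0854; 3 rose and 5 fell adjusted over the list alone). The jasmonate synthesis genes AOS (93.7 ± 16.3 to 29.9 ± 9.29) and AOC1 (23.9 ± 3.66 to 10.1 ± 1.95) fell. The defence-induced kinase gene FRK1 (0.687 ± 0.0590 to 4.71 ± 1.73) and JAZ1, a repressor of jasmonate signalling (7.25 ± 1.14 to 12.1 ± 1.97), rose. The calls on C4H, LDOX, MYBL2 and JAZ1 were lost in 7, 5, 4 and 3 of the 13 other settings (adjusted p up to 0.107, 0.102, 0.0722 and 0.0722).

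Of 12 cold, drought and ABA genes, COR47 rose (202.5 ± 39.3 to 316.3 ± 52.6) and RD22 fell (209 ± 18.7 to 140.0 ± 16.0), the only 2 to pass, also when adjusted over the list alone (camera adjusted p = 0.834). The median of this list was 0.21 and its mean -0.02, and camera placed it lower where fry placed it higher (adjusted p = 0.918). The median was 0.066 without a filter, 0.078 without hid1 replicate 3 and -0.069 without WT replicate 2, and camera placed the list higher without WT replicate 1 or hid1 replicate 2. Of 4 heat shock genes HSP70-4 fell (15.1 ± 3.09 to 9.15 ± 0.673), also the only call adjusted over the list alone (camera adjusted p = 0.147). The calls on COR47 and HSP70-4 were lost in 7 and 3 of the 13 other settings (adjusted p up to 0.0823 and 0.0664).

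Among lists for other organs or seeds, 9 root and root hair genes were tested, of which 3 rose, 1 fell and 5 did not pass (camera adjusted p = 0.217; 7 rose and 1 fell adjusted over the list alone). EXPA7, a root hair expansin (4.17 ± 2.59 to 11.3 ± 3.02), PRP3, a root hair wall protein (30.1 ± 19.8 to 74.9 ± 33.4), and SCR, a factor of root patterning (14.0 ± 0.910 to 18.9 ± 1.51), rose, and IRT1, the root iron transporter, fell from 36.2 ± 12.3 to 6.26 ± 1.46. The calls on SCR, PRP3 and EXPA7 were lost in 10, 8 and 3 of the 13 other settings (adjusted p up to 0.146, 0.152 and 0.0739). WT replicate 1 stood apart here as well: the mean log2 value of the 8 markers other than IRT1 was 3.48 in it, 2.46 and 2.52 in the other WT libraries, and 3.89, 3.44 and 3.59 in the hid1 libraries. Without WT replicate 1 the root list passed with the preset correlation (camera adjusted p = 0.00446); over all libraries it did not pass with an estimated correlation either (adjusted p = 0.908). None of 6 seed maturation genes passed, PER1 being at 4.45 ± 2.45 and 7.60 ± 2.07 (adjusted p = 0.109) and EM6 at 4.24 ± 2.99 and 4.22 ± 1.202 (adjusted p = 0.845), with a camera adjusted p of 0.752 for the list. None of 7 guard cell and stomatal lineage genes passed, including TMM (11.4 ± 0.272 and 15.7 ± 2.47, adjusted p = 0.0606) and MYB60 (9.25 ± 1.34 and 9.81 ± 1.24, adjusted p = 0.757). The camera adjusted p of that list was 0.84, with a median of 0.03 and a lower placement by camera against a higher one by fry (adjusted p = 0.686). Its direction was not stable: the median lay between -0.064 (without hid1 replicate 3) and 0.125 (without hid1 replicate 1), and camera placed the list higher without WT replicate 3. Neither the seed maturation nor the guard cell list gained a call when adjusted over the list alone.

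**Figure D3:**
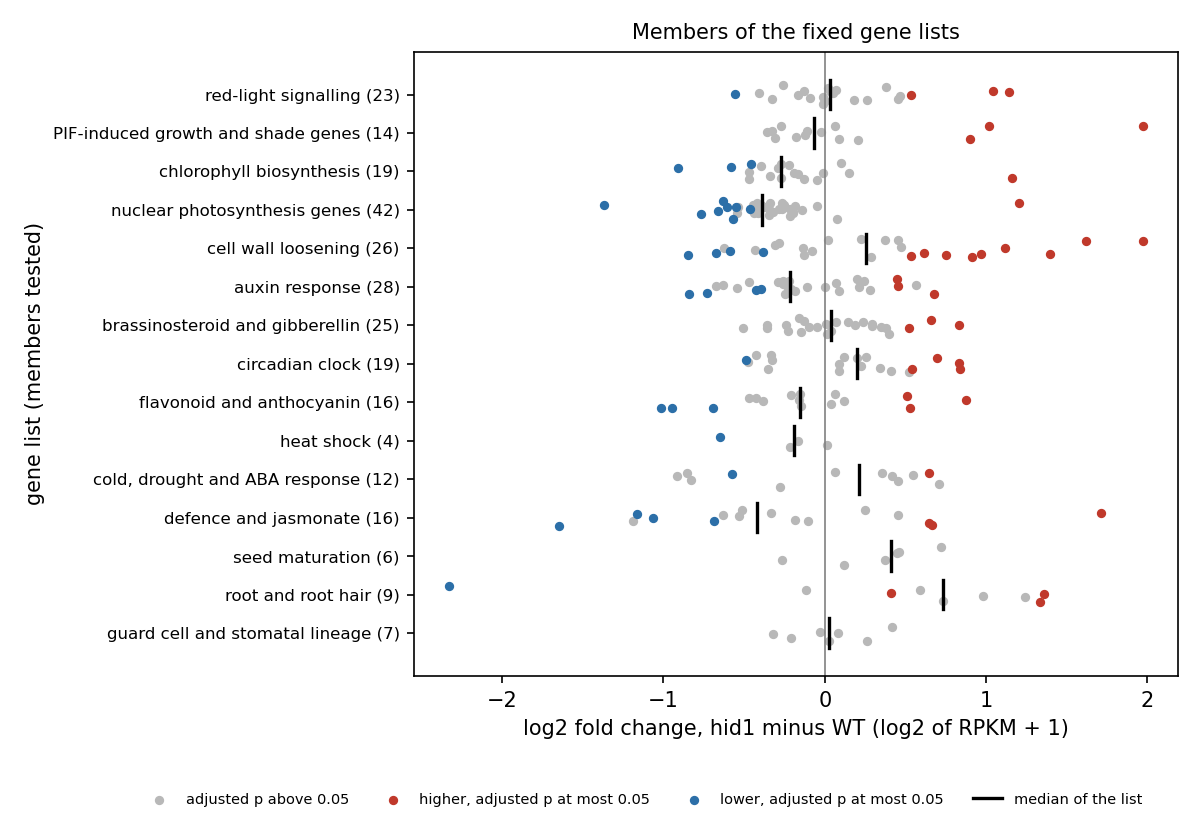
Log2 fold change (hid1 minus WT, log2 of RPKM + 1) of every tested member of the 15 fixed gene lists; each point is a gene, coloured points passed an adjusted p of 0.05, and black marks are list medians. The photosynthesis list lies mostly left of 0 (median -0.39), and cell wall genes spread to both sides (9 rose, 4 fell).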

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

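The scaling by median ratios and the removal of a length trend were chosen after seeing the data, the other settings before. No changed gene took the opposite sign under any setting tried. Whether the replicate number pairs the libraries was not settled. The correlations of deviations from the genotype means between same-numbered libraries were 0.315, 0.061 and 0.105. That of replicate 1 was the highest of any WT and hid1 pair, but WT replicate 2 correlated best with hid1 replicate 3 (0.255). On the second principal component only the replicate 1 libraries were positive (31.9 in WT, 12.14 in hid1). An effect shared by the replicate 1 libraries therefore stays open. With the replicate block the count was 3635 changed genes (2384 higher, 1251 lower), 669 of them over 2-fold, and 4 lists passed, with defence and jasmonate and root and root hair joining at an adjusted p of 0.0352 each. The count of changed genes was 2553 with a pseudocount of 0.1, 2554 with 5, 1819 without a filter, 2648 with quantile normalization, 2569 with median-ratio scaling and 2574 with the length trend removed. The lower genes numbered 492 without a filter, where more genes were tested, 1343 with quantile normalization and 1236 with median-ratio scaling, against 794. A pseudocount of 5 left 282 genes over 2-fold (211 higher, 71 lower), since it shrinks the fold of low genes, and a pseudocount of 0.1 gave 915. Leaving out a library gave 1430 to 3260 changed genes (1021 to 2289 higher, 395 to 971 lower) and 573 to 814 over 2-fold. The counts were 3260 without WT replicate 1, 1430 without WT replicate 2, 1562 without WT replicate 3, 1764 without hid1 replicate 1, 1517 without hid1 replicate 2 and 1614 without hid1 replicate 3. The cause of these differences in the counts was not tested.

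With an estimated correlation 0 lists passed (camera adjusted p = 0.688 for both chlorophyll and photosynthesis). With fry for a common direction 0 lists passed (adjusted p = 0.0855 for both). Without regard to direction most of the 15 lists passed fry, among them chlorophyll (adjusted p = 0.00125) and photosynthesis (0.0145). Both lists passed under quantile normalization (0.00899 and 0.0121), median-ratio scaling, the replicate block and without each library in turn. Further lists passed without a library: root and root hair without WT replicate 1 (leave-one-out range 0.00446 to 0.508), defence and jasmonate without WT replicate 2 (0.0265 to 0.178), flavonoid and anthocyanin without WT replicate 3 (0.0207 to 0.614) and auxin response without hid1 replicate 1 (0.0444 to 0.266). Of 73 named genes, 64 passed the threshold, 43 of them under every setting, and none changed direction past it. Without a library the named calls lost were 3 (WT replicate 1), 13 (WT replicate 2), 12 (WT replicate 3), 11 (hid1 replicate 1), 16 (hid1 replicate 2) and 12 (hid1 replicate 3). The planned settings for counts and for organellar genes were not run, as the values are RPKM of nuclear genes, and depth limits mainly the low genes.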

Other observations

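All gene lists in this part, and all its tests apart from the main limma calls on single genes, were chosen after the largest changes had been seen. The lists cover glucosinolate synthesis, nutrient responses and carbon starvation. At the preset correlation each of the 7 lists passed (camera adjusted p between 2.03e-31 and 0.00051). With an estimated correlation the camera adjusted p was 0.0922 for each, so the set calls were lost. The counts below are of single genes. Of 23 tested genes of aliphatic glucosinolate synthesis, which makes methionine-derived defence compounds, 22 fell and 1 did not pass. BCAT4, the first enzyme of the pathway, fell from 23.5 ± 5.76 to 2.99 ± 0.538 RPKM (limma adjusted p = 2.2e-05), CYP79F1 from 13.9 ± 1.88 to 1.82 ± 0.527, and the regulator MYB28 from 23.4 ± 1.15 to 13.9 ± 1.29. Of 12 indole glucosinolate genes, 4 fell and 1 rose. Of 19 phosphate starvation genes, 13 fell and none rose, among them SPX1 (27.3 ± 6.06 to 8.23 ± 3.13) and SQD2, a sulfolipid synthase (39.6 ± 8.19 to 16.1 ± 3.24). Of 13 sulfur limitation genes 10 fell, including APR1 (40.8 ± 4.63 to 17.2 ± 4.07), and of 15 iron deficiency genes 9 fell, including IRT1, also on the root list, and the reductase gene FRO2 (6.67 ± 0.795 to 1.81 ± 0.518).

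Of 17 genes induced by sugar starvation or darkness, 15 rose and none fell, among them SEN1 (58.1 ± 28.2 to 345.7 ± 44.0), BCAT2 (4.09 ± 1.15 to 31.8 ± 8.42) and PRODH1 (61.9 ± 10.9 to 173.9 ± 19.8). This list holds 2 of the 20 largest changes, ASN1 and THA1. None of the 7 lists has a direction independent of how it was chosen, since all were written after changes had been seen. Of 10 genes of seed oil mobilization, 8 rose, including ICL, the isocitrate lyase of the glyoxylate cycle (12.7 ± 2.54 to 58.4 ± 12.7). The fry adjusted p of the 7 lists, which does not compare a list with other genes, lay between 0.00124 and 0.0155. Because the lists were written from these same data, these values add no independent evidence for a set change.

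The mostly lower calls in the nutrient and glucosinolate lists, and the higher calls in the sugar starvation and seed oil lists, were weighed against 3 explanations. The authors' scaling of the libraries is argued against for these calls, since 98.8% of the 82 called members kept call and direction under quantile normalization. Of all 2569 changed genes, 2067 kept their call. The lists were written after large changes had been seen, which favours a high share among their members. A smaller share of root tissue in the hid1 samples would lower root markers. Those other than IRT1 were instead higher by 0.817 on the log2 scale, but WT replicate 1 (3.48) overlapped hid1 replicate 2 (3.44), so this stays open. A larger share of root tissue in hid1 would go with these markers and with the lower photosynthesis genes of the report, but not with the fall of the iron-uptake genes IRT1 and FRO2, known from roots; it was not tested and stays open. A growth or handling difference between the WT and hid1 cultures cannot be told apart from genotype, because the sample characteristics give 0 kinds of entry beyond genotype with light condition and age, and the replicate numbers name no culture. An effect of hid1 itself stays open, untested.

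AT2G35744, AT2G35747 and AT2G35750, within 15029712 to 15030348 of chromosome 2 (TAIR10.1), were listed at 0 in every hid1 library. They may belong to the mutated locus itself, since the name table does not place HID1. Too few reads is argued against: at the WT level at least 9.9 reads would be expected over each in every hid1 library, by the estimated depth. Elsewhere 0 features were at 0 in all hid1 libraries with a WT mean of at least 5 RPKM, and 0 features showed the opposite. The neighbour AT2G35760 rose from 10.1 ± 0.741 to 34.2 ± 0.946. A lesion in this segment of the hid1 genome and loss of transcription without one cannot be told apart. The segment was bounded by these features themselves and holds no other annotated feature to compare. Gene-level values also hold no reads to show a breakpoint.

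On chromosome 4, 7 neighbouring genes from AT4G22485 to AT4G22520 were lower in hid1, while AT4G22470 beside them rose from 17.62 ± 3.27 to 124.6 ± 30.3 RPKM. Reads moved between these 8 neighbours alone would leave their sum alike. The length-weighted sum over all 8, the RPKM times exon length, was instead 4.02 times higher in WT. It was 834.3 ± 114.5 RPM in WT against 207.5 ± 45.7 in hid1, with overlapping genes counted in each. The sum left out family members elsewhere, such as EARLI1 and AT4G12500, which rose. Reads shared with those members were not tested. Loss of the whole block from the hid1 genome cannot be told apart from lower transcription: AT4G22490 kept 22.9% of its WT level, which reads of similar copies might supply. An effect of hid1 on this cluster stays open as well.

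Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many changed genes as the real one, which was the real split itself. It gave 2569 genes, 643 of them over 2-fold, and the highest of the others gave 0 for both. The splits are too few for a share under 0.05. Each of the others also mixes the genotypes, so a genotype difference widens the spread within its groups and makes calls unlikely.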
